A study of Oryza sativa with 4 samples.

How the data were processed

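Total RNA from panicle primordia of the rice cultivars Pusa 1266 and Pusa Basmati 1, at the stage the labels number 0, had been extracted with TRIzol, and biotin-labelled cRNA made from 8 ug of it had been hybridized to Affymetrix arrays. The deposited table held 1 linear signal intensity per probe set and array for 57381 probe sets, made with GCOS 1.2 per the submitters' processing notes. The background treatment and any scaling are not given in the sources used here. The values ran from 0 with 1 decimal, and the trimmed means of the 4 arrays (2% taken off each end) differed by up to 1.98 times, so the deposited table had not been brought to 1 common level. Arrays give no counts, and the number of arrays limits the precision. The series has no column for any other sample.

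The samples were grouped by the cultivar named in their titles. The titles say low grain number for both cultivars, whereas the characteristic and the description say high for Pusa 1266 and low for Pusa Basmati 1, so no group was named by its grain number. The series describes 2 biological replications, and the replicate numbers were not treated as pairs, because the differences between replicate 1 and replicate 2 in the 2 cultivars correlated across probe sets with a Pearson r of only 0.0181 (0.0685 with the deposited scaling).

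The tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Because the arrays were not on 1 level, the rule called for log2 of the signal plus 16 followed by quantile normalization in limma 3.58.1 under R 4.3.3. The 123 control probe sets were left out of the tests, and of the other 57258 the 30029 that exceeded the median of their array on at least 2 of the 4 arrays were tested. Differences were computed as Pusa 1266 minus Pusa Basmati 1 with lmFit and eBayes with a trend in limma, with Benjamini-Hochberg adjustment and a threshold of 0.05. A count at 2-fold or more was kept beside it. Where the signals of a cultivar lay below the added constant of 16, the size of a log2 difference depends on that constant, and values with pseudocounts 1 and 64 or the signals are given with it. With 2 arrays against 2, an exact permutation test of a single value cannot go below a two-sided p of 0.333, so no such test was run, and the calls rest on the variance that limma shares across probe sets. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

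Probe sets were joined to genes through the identifiers of the array annotation. It gave 1 gene for 22436 probe sets, several for 95 and none for 34727. These were 17905 genes, of which 2458 carried a name beyond a locus number or clone identifier. The reference annotation, assembly ASM3414082v1 of a Japonica rice, served for names, chromosomes, gene order and gene span, and no coordinates are given because the build behind the array is not stated. Each gene was represented by its probe set with the highest mean over all 4 arrays, chosen without regard to cultivar, which left 15183 tested genes.

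Of 22 planned gene lists 19 held at least 3 tested genes. The planned loci and descriptions were translated to gene symbols and synonyms, since the annotation gave no descriptions or locus identifiers of the planned kind, and this was done before any difference between the cultivars was computed. Of the planned loci, 7 of 22 were matched for panicle architecture, 14 of 20 for flowering time and the clock, 4 of 4 for inflorescence MADS genes, 13 of 13 for floral organ identity and 3 of 3 for loci of cultivar traits. RCN1 and IDS1 were left out because the annotation gave their symbols to other genes. Lists of KNOX homeobox, SPL, cytokinin, auxin, gibberellin, ethylene-responsive factor (ERF), cell cycle, histone, cytosolic ribosomal protein, photosynthesis, vascular and cell wall, heat shock, WRKY and pathogenesis-related genes were matched by symbol. Peroxidases (2 tested genes) and disease resistance genes (1 tested gene) were too few to test as lists, and no gene matched the list of transposon-related genes. The photosynthesis and vascular lists were planned to stand for other tissue in the dissection, and the floral organ list for a later stage. The vascular list took cellulose synthase genes without regard to cell type, so its fall does not by itself mark vascular tissue. Lists were compared with all other genes by camera in limma, with a preset inter-gene correlation of 0.01. Benjamini-Hochberg adjustment was made over the 19 lists. Alternatives were camera with an estimated correlation and fry, which tests whether a list's genes move on balance to 1 side. With 4 arrays the estimated correlation leaves camera few degrees of freedom, so hardly any list could pass, whatever its correlation.

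The genes named in the text were set by a rule. It took every member of the panicle architecture, flowering time, inflorescence MADS, floral organ and cultivar trait lists that passed over all genes or adjusted over the list alone, and the 2 with the smallest p where none passed. It also took the 12 highest and the 12 lowest differences among genes past the threshold whose cultivars did not overlap and that had a name. Of each other list it took 2 to 4 members with the smallest p, which was applied as 4 for lists called by camera and 2 for the rest. The condition of an informative description was read as a name beyond a locus number, because no descriptions were available. Members named outside this rule, and those named to show which members did not pass or went the other way, were chosen after their values were seen.

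Clustering along the chromosomes was measured as the share of called genes whose next tested gene was also called, against 10000 random reassignments of the calls, and the called share of each chromosome was compared with the rest by Fisher's exact test. RNA quality was read from the ratio of the signals at the 3' and 5' ends of control transcripts. Alternatives were the deposited scaling, centring each array on its median, pseudocounts 1 and 64, no filter and a filter at a higher percentile, a replicate block, leaving out each array, eBayes without trend or with the robust option, a test against a minimum fold of 1.5, leaving out probe sets that match several transcripts, and a mean over all probe sets of a gene. Clustering was also run without neighbouring copies of a gene and probe sets that match several transcripts, both left out at once. Copies were recognised by a shared name, and only 2458 of the 17905 genes carried a name, so unnamed copies stayed in. Clustering at 2-fold or more and list medians relative to all genes were added after the data were seen. The procedure was tested on simulated data with the variance of these arrays, in 5 simulations of 200 changed probe sets each. It recovered 8.96% of changes of 1.5-fold, 35.2% of 2-fold and 68.8% of 4-fold, with a mean of 1 false call per simulation, and camera called the shifted list in 5 of 5 and the unshifted list in 0 of 5. Only 200 of 30029 probe sets were changed, against 16046 called in the real data, where the adjusted threshold was therefore less strict. These rates hold for sparse changes and do not describe the calls of the real comparison. The simulated probe sets were drawn independently of one another, so the simulated lists had no inter-gene correlation. The camera result therefore does not test how lists of correlated genes are called with the preset correlation.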

Results

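RNA from the panicle primordia of 2 Indica rice cultivars, Pusa 1266 and Pusa Basmati 1, was measured on 4 Affymetrix arrays, with 2 biological replicates per cultivar. The median signal per array was 6.8 and 7.8 in Pusa 1266 and 11.5 and 11.3 in Pusa Basmati 1. The trimmed mean was 78.0 and 89.1 in the first cultivar and 138 and 155 in the second, and signals of 16 or less made up 62.5%, 60.8%, 55.3% and 55.2% of the probe sets. After normalization the replicates of Pusa 1266 correlated with r = 0.991 and those of Pusa Basmati 1 with r = 0.994 across probe sets, which are not independent observations. Arrays of different cultivars correlated with r between 0.902 and 0.904. The SD of the log2 difference was 0.259 and 0.213 within the cultivars and between 0.845 and 0.854 across them.

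The 3' to 5' signal ratios of the control transcripts, a sign of RNA integrity, were higher in both Pusa 1266 arrays than in both Pusa Basmati 1 arrays for all 5 controls. For GAPDH the ratio was 19.4 ± 1.28 (SD, n = 2) in Pusa 1266 and 8.03 ± 0.669 (n = 2) in Pusa Basmati 1, which is 2.42 times higher. The actin ratio was 1.85 times higher, that of a second actin design 3.25 times, that of cyclophilin 1.24 times and that of ubiquitin 1.42 times. The ratio therefore moved with cultivar in every comparison that follows.

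**Figure D1:**
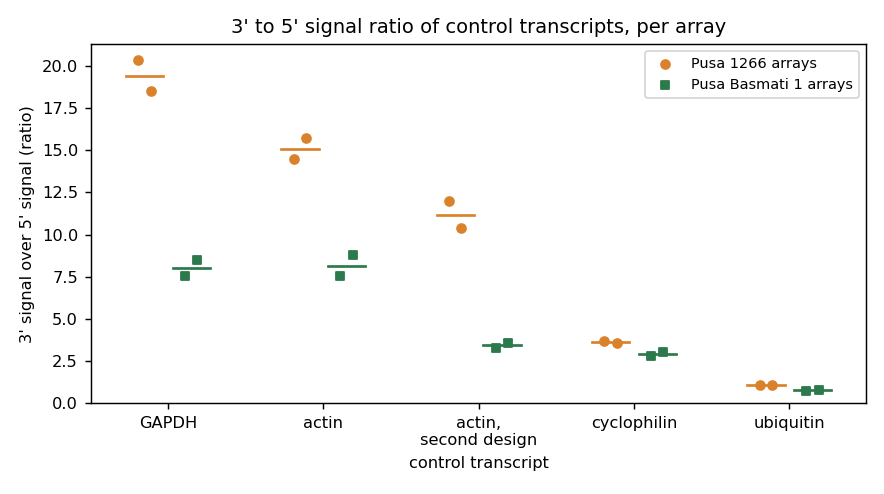
Ratio of the 3' to the 5' signal (y axis, no unit) of 5 control transcripts (x axis), with 1 point per array and a line at the mean of each cultivar. Both Pusa 1266 arrays lie above both Pusa Basmati 1 arrays for each transcript, with means of 19.4 and 8.03 for GAPDH.

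The single comparison of the series asks which transcripts differ between the young panicles of cultivars whose characteristic labels give a high grain number per panicle for Pusa 1266 and a low one for Pusa Basmati 1, although the sample titles call both low. Among genes of the panicle meristem RFL (APO2), the rice counterpart of LEAFY, was 6.13-fold higher in Pusa 1266, and LAX1, a bHLH regulator needed for axillary meristems, 2.96-fold. The flowering regulator MADS56 was 5.18-fold higher, and the type A cytokinin response regulator RR1 was 3.91-fold higher. RFL, LAX1 and MADS56 had no other tested probe set, so probe sequence was not checked for them. Of the JAZ genes, whose proteins repress jasmonate signalling, JAZ10 was 20.9-fold and JAZ12 14.8-fold lower in Pusa 1266, while EG2 (JAZ1) rose by 0.62 on the log2 scale (n = 2 per cultivar throughout). The gene of the small heat shock protein HSP18.1 was 24.1-fold lower, and 7 of 8 photosynthesis genes and 32 of 42 heat shock genes fell. The probe sets of JAZ10 and HSP18.1 are of the kinds that match several transcripts, so their folds may not belong to 1 gene alone. The other tested probe set of each was also called lower. These folds follow quantile normalization, and the log2 differences with the deposited scaling were 1.88 for RFL, 0.77 for LAX1, 1.69 for MADS56, 1.198 for RR1, −4.98 for JAZ10, −4.61 for JAZ12, 0.09 for EG2 and −5.19 for HSP18.1.

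Of the 30029 probe sets tested, 16046 (53.4%) passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 8472 higher and 7574 lower in Pusa 1266. At 2-fold or more there were 1707 higher and 2290 lower. By gene, 5284 of 15183 were higher and 3972 lower, with 845 and 1099 at 2-fold or more and 67 and 101 at 8-fold or more. The cultivars did not overlap at 76.3% of the tested probe sets, where chance gives 33.3%. The direction of small differences rested on the scaling between arrays: with the deposited scaling 1646 probe sets were higher and 17956 lower, and with each array centred on its median 2906 were higher and 13660 lower. The counts at 2-fold or more moved too, to 619 higher and 7347 lower with the deposited scaling. With median centring they were 849 and 4802. The median log2 difference of all genes was 0.07 after quantile normalization, −0.62 with the deposited scaling and −0.38 with median centring. Several directions that turned are therefore also given relative to that median. Relative to it the 2 other scalings give equal values, because median centring only moves each array by a constant. The array medians, with signals of 6.8 to 11.5, lay below the added constant of 16. Median centring was therefore set by dim probe sets and did not bring the tested genes to 1 level.

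Among the named genes furthest apart, those higher in Pusa 1266 included the kinesin gene KIN14R (LOC4352796, chromosome 12) at 3.83 ± 0.10 on the log2 scale (SE, adjusted p = 9.19e-08) and the pectin methylesterase inhibitor gene PMEI28 (LOC4344463, chromosome 8) at 3.72 ± 0.12. SPO11-4, of the family of topoisomerases that cut DNA in meiosis, rose by 3.51 ± 0.06. KIN14R, PMEI28 and SPO11-4 stood at 3.13, 3.06 and 2.80 with the deposited scaling. The RNA-dependent RNA polymerase gene RDR4 (2.90), the protein kinase gene PID, whose Arabidopsis counterpart directs auxin transport (2.70), the leucine-rich repeat gene IRL3 (2.69), RFL (2.62), MADS56 (2.37), BCL1 (2.35) and the membrane channel gene NIP1-1 (2.35) also rose. In H2B.10, a histone H2B gene, and MADS20 the Pusa Basmati 1 signals were below the constant of 16 added before logs were taken, so the size of the rise is not fixed by the data. Signals of H2B.10 were 1476 and 1764 against 1.9 and 3.0, and its value of 6.82 became 9.43 with pseudocount 1 and 4.98 with pseudocount 64. For MADS20, with signals of 93.1 and 98.5 against 6.2 and 0.4, the value of 2.99 became 5.53 and 1.56.

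Among the genes lower in Pusa 1266, JAZ10 stood at −4.38 ± 0.06 on the log2 scale (SE, adjusted p = 9.75e-09) and JAZ12 at −3.89 ± 0.07. BHLH148, a transcription factor known to bind JAZ proteins, stood at −4.19, and HSP18.1 at −4.59. The calmodulin-like gene CML27 (−3.90), the brittle culm 1-like gene BC1L9 (−3.53) and ACO1, of the last step of ethylene synthesis (−3.52), fell as well. The other tested probe set of CML27 was not called in either direction. In WRKY71, WRKY24, JAZ9, JAZ11 and the dehydrin gene RAB21, which is induced by abscisic acid and drought, the Pusa 1266 signals were below the added constant. WRKY71, a transcription factor of defence, had signals of 10.3 and 2.1 against 2212 and 2516, and its value of −6.33 became −8.03 with pseudocount 1 and −4.76 with pseudocount 64. Signals of JAZ9 were 12.5 and 11.6 against 782 and 880.2. All 24 genes kept their sign under the deposited scaling, under median centring and with both pseudocounts. The largest differences of all tested genes belonged to genes without a name and also had a side below the added constant, LOC9266843 at 7.16 and LOC4333210 at −7.66. Another probe set of LOC4333210 was called in the opposite direction, at 6.08.

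**Figure D2:**
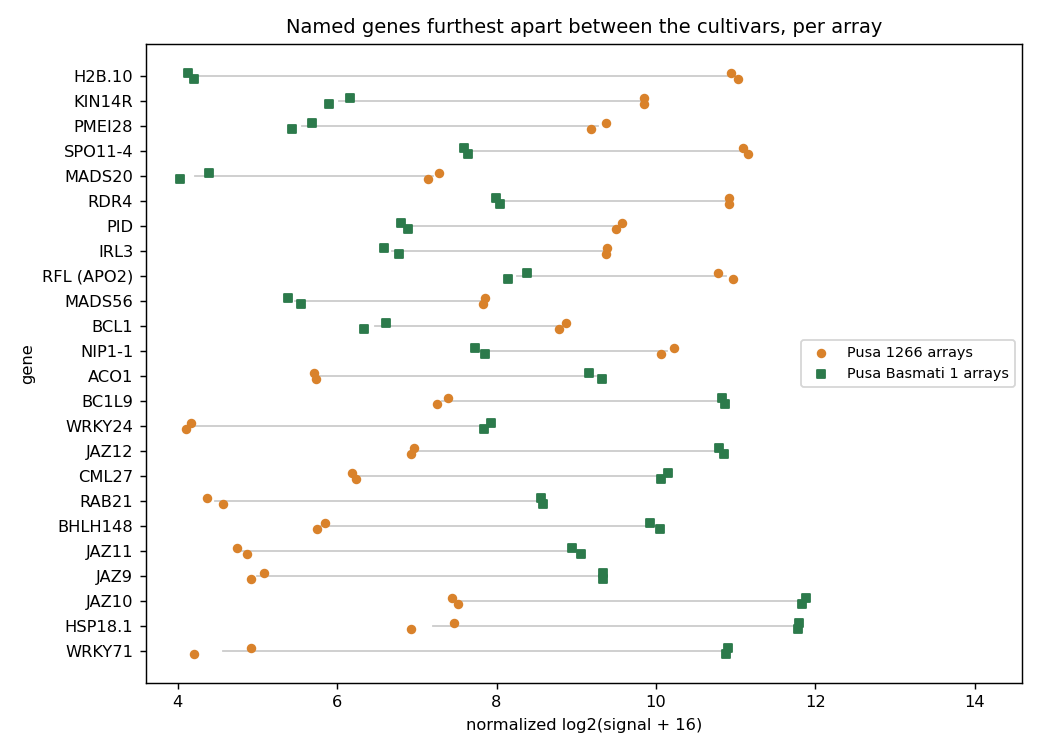
Normalized log2(signal + 16) on each array (x axis) of the 12 highest and 12 lowest named genes (y axis), with orange circles for Pusa 1266 and green squares for Pusa Basmati 1. The replicates of a cultivar lie closer together than the cultivars for each gene, and the gaps of H2B.10, MADS20, WRKY71, WRKY24, JAZ9, JAZ11 and RAB21 depend on the constant of 16, since their lower signals were below it.

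Of the 6 tested genes of panicle architecture 4 rose and none fell in Pusa 1266, with the same 4 adjusted over the list alone. RFL rose by 2.62 ± 0.09 (SE, n = 2 per cultivar), with signals of 1312 and 1681 against 402 and 384, and LAX1 by 1.57 ± 0.10. SPL14 (IPA1), which promotes panicle branching, rose by 0.58 ± 0.05, and FON1, a receptor kinase that restrains the floral meristem, by 0.47 ± 0.10. With the deposited scaling SPL14 stood at −0.14 and FON1 at −0.35, which were above the median of all genes by 0.48 and 0.27. LOG, an enzyme that activates cytokinin, and GW2, a ubiquitin ligase of grain width, stood at −0.10 and −0.09 and did not pass. The list had a median of 0.53 and did not pass as a whole (camera, adjusted p = 0.151). Its median turned to −0.24 with the deposited scaling and −0.01 with median centring, 0.37 above the median of all genes in both.

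Among genes of flowering time and the circadian clock 6 of 13 rose and 2 fell, or 7 and 2 adjusted over the list alone, and the list did not pass (median 0.35, adjusted p = 0.263). With the deposited scaling the list median turned to −0.37, with 8 of the 13 below 0. With median centring it was −0.14, with 7 below 0, and in both it lay 0.24 above the median of all genes. MADS56 rose by 2.37 ± 0.12 (1.59 with pseudocount 64) and PRR1, the counterpart of the evening clock gene TOC1, by 1.26 ± 0.12 (0.47 with the deposited scaling). The clock genes PRR95 and GI rose by 0.94 ± 0.06 and 0.92 ± 0.08, while LHY (CCA1), which peaks at dawn, fell by 0.60 ± 0.05. DTH8 (Ghd8) passed at 0.76 ± 0.18, but its signals lay between 4.3 and 16.2, so the size depended on the added constant (1.81 with pseudocount 1 and 0.28 with pseudocount 64), and its adjusted p in limma was 0.0678 without the first Pusa Basmati 1 replicate, where the value was 0.65. The phytochrome gene PHYC fell by 0.48 ± 0.07. PHYA rose by 0.35, turned to −0.37 with the deposited scaling and −0.14 with median centring, and had another probe set called in the opposite direction. MADS50 passed adjusted over the list alone (0.27, adjusted p = 0.0507 over all genes) and stood at −0.54 with the deposited scaling and −0.30 with median centring, and Hd1 at 0.42 did not pass. The hours at which the panicles were taken are not given in the sources used here.

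Inflorescence MADS genes went both ways: MADS34 (PAP2), which acts in the switch to spikelets, fell by 0.83 ± 0.08, while MADS18 rose by 0.44 ± 0.05 and MADS15 by 0.15 ± 0.05. MADS14 at −0.12 did not pass, but all 3 of its other probe sets were called lower. The counts adjusted over the list alone were also 2 up and 1 down. The list had a median of 0.01, a mean of −0.09 and an adjusted p of 0.887 in camera, which gave its direction as down. With a mean over all probe sets of each gene the median was −0.41, and the list still did not pass. MADS18 and MADS15 turned negative with the deposited scaling (−0.29 and −0.35) and stood above the median of all genes. Other probe sets of MADS15 were called in both directions, and its adjusted p in limma reached 0.185 without the first Pusa 1266 replicate, at 0.13.

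Floral organ identity genes, which mark a later stage, gave small differences. Of 13 genes 4 rose, 3 adjusted over the list alone, and none fell, with a median of 0.11 (adjusted p = 0.495). These were MADS4 (0.48 ± 0.11), MADS58 (0.34 ± 0.10), MADS2 (0.27 ± 0.06) and MADS5 (0.21 ± 0.07). Without the first Pusa 1266 replicate MADS58, MADS2 and MADS5 did not pass (0.34, 0.23 and 0.18). All 13 lay below 0 with the deposited scaling and with median centring, where 7 of the 13 lay above the median of all genes. The loci of cultivar traits had 2 of 3 genes higher, or 3 of 3 adjusted over the list alone (median 0.55, adjusted p = 0.263). BADH2, whose loss gives fragrant rice, rose 2.82-fold (SE 0.12 on the log2 scale), with signals of 103 and 141 against 66 and 65, and its log2 difference was 0.75 with the deposited scaling. SD1 (GA20ox2), the semidwarf gene of gibberellin synthesis, passed at 0.53 ± 0.18 with signals between 10 and 17, near the added constant (1.04 with pseudocount 1 and 0.21 with pseudocount 64), with an adjusted p of 0.197 without the first Pusa Basmati 1 replicate, where it stood at 0.45. Wx, of amylose synthesis, stood at 0.55 ± 0.21 and passed in limma adjusted over the list alone (0.0295). The list median of 0.55 became 1.09 with pseudocount 1 and 0.22 with pseudocount 64, so its size depended on the added constant.

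The remaining developmental and hormone lists held members of both directions, and none passed camera. Of the KNOX homeobox genes, which maintain meristems, 3 of 8 rose and 1 fell (adjusted over the list alone also 3 and 1, median 0.25, adjusted p = 0.263), led by OSH45 at 1.31 and OSH71 at 1.02. Of 11 SPL genes 5 rose and 2 fell (5 and 2 adjusted over the list alone, median 0.24, adjusted p = 0.391), with SPL7 at 1.14 and SPL15 at −0.92. In the cytokinin list 11 of 27 rose and 3 fell (11 and 3 adjusted over the list alone, median 0.11, adjusted p = 0.487). RR1 rose by 1.97 ± 0.13 and RR2 by 1.36 ± 0.11. Among 47 auxin genes 18 rose and 9 fell (20 and 9 adjusted over the list alone, median 0.16, adjusted p = 0.391), with the repressor IAA7 at 1.36 and the response factor ARF7 at 1.13. For gibberellin 3 of 5 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.41, adjusted p = 0.391). The DELLA gene SLR1, a brake on gibberellin signalling, rose by 1.23 ± 0.08 and the receptor gene gid1 by 0.41, which turned to −0.31 with the deposited scaling and −0.08 with median centring. The values of other genes were also lower with the deposited scaling, at 0.50 for OSH45, 0.63 for RR2, 0.55 for IAA7, 0.37 for ARF7 and 0.44 for SLR1. PRR95, GI, OSH71 and SPL7 kept their sign but did not pass with the deposited scaling (0.17, 0.14, 0.21 and 0.32). With that scaling the medians of the KNOX, SPL, cytokinin, auxin and gibberellin lists lay below 0 and remained above the median of all genes. Of the 47 auxin genes 43 then lay below 0 and 16 below the median of all genes. Of the 27 cytokinin genes these were 21 and 12.

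Cell cycle genes were mixed, with 12 of 26 up and 7 down (13 and 8 adjusted over the list alone, median 0.17, adjusted p = 0.558), and the D-type cyclins CYCD3-2 and CYCD5-1 rose by 1.64 and 1.51, or 0.86 and 0.73 with the deposited scaling. Of 5 histone genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, median 0.22, mean 1.45, adjusted p = 0.263). H2B.10 carried that mean, with Pusa Basmati 1 signals of 1.9 and 3.0 that leave its size to the added constant, and H2B.11 rose by 0.38, with −0.31 under the deposited scaling. The histone list passed with the deposited scaling (adjusted p = 9.34e-05, median −0.31, mean 0.96) and with median centring (6.15e-05, median −0.08), within a range up to 0.609 over the alternatives. Of 23 cytosolic ribosomal protein genes 4 rose and 4 fell (3 and 4 adjusted over the list alone, median −0.03, adjusted p = 0.556), among them RPL18 at −0.56 and RPS3A at −0.25. With the deposited scaling 22 of the 26 cell cycle genes and all 23 ribosomal protein genes lay below 0, and 13 and 7 of them below the median of all genes.

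Heat shock genes, which encode chaperones and the factors that induce them, formed the list with the smallest p. In Pusa 1266 32 of 42 fell, 18 of them by 2-fold or more, and 3 rose, with the same counts adjusted over the list alone. The median was −0.72 (camera, adjusted p = 4.47e-10), and the adjusted p was 0.407 with an estimated correlation, the highest over the alternatives, of which the lowest was 3.07e-11. HSFB2B (−2.91 ± 0.08), HSP16.9A (−2.67 ± 0.06), HSP16.9B (−2.30 ± 0.06) and HSP23.2 (−2.23 ± 0.06) fell, whereas HSP81-3 (0.19), HSFC1B (0.50) and HSFB4B (0.54) rose. With the deposited scaling 41 of the 42 lay below 0 and 34 below the median of all genes. The 3' to 5' ratio was higher in the same arrays, for GAPDH by 2.42 times.

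WRKY transcription factors fell in 5 of 6 cases, with 5 adjusted over the list alone and none up. Their median was −0.64 and their mean −2.02 (adjusted p = 0.00418), and the adjusted p was 0.407 with an estimated correlation, against 0.0114 or less in the other camera alternatives, whose medians ran from −2.10 with the filter at a higher percentile to −0.38 with pseudocount 64. WRKY71 and WRKY24 made most of the mean, and since both had Pusa 1266 signals below the added constant of 16, the size of the mean depends on it. WRKY9 (−0.45) and WRKY51 (−0.41) fell, and WRKY62 at −0.32 did not pass. Of 8 ERF genes 7 fell, 3 by 2-fold or more, and 1 rose, also adjusted over the list alone (median −0.96, adjusted p = 0.00769). The adjusted p was 0.407 with an estimated correlation and 0.136 with the filter at a higher percentile, and the lowest over the alternatives was 0.00189. Their median was −1.48 with pseudocount 1 and −0.62 with pseudocount 64. ERF25 (−2.73 ± 0.11), ERF24 (−1.78 ± 0.12), ERF30 (−1.48 ± 0.14) and ERF31 (−0.98 ± 0.08) fell. ERF30 signals in Pusa 1266 were 16.9 and 16.4, near the added constant, and its value was −0.85 with pseudocount 64. These 4 genes and the other 3 that fell also carry DREB names, those of factors known from cold and drought responses, while EREBP1 rose by 0.25. With the deposited scaling all 8 lay below 0, and 7 of them below the median of all genes. The control ratios stood as for the heat shock genes, with cyclophilin at 1.24 times and the second actin design at 3.25 times.

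Photosynthesis genes, included as markers of green tissue, fell in 7 of 8 cases, 6 of them by 2-fold or more, with 7 adjusted over the list alone and none up. The median was −1.26 (adjusted p = 8.47e-04), and the adjusted p was 0.408 with an estimated correlation, against 0.00296 or less in the other camera alternatives and 0.00588 in fry, which does not compare the list with other genes. The light-harvesting genes RCABP69 (−2.19 ± 0.11), LHCP (−1.92 ± 0.11) and CAB2R (−1.19 ± 0.06) fell, as did the oxygen-evolving complex gene OEE3 (−1.26 ± 0.08). PSAG, of photosystem I, stood at 0.05 ± 0.09 and did not pass, and with both other scalings all 8 lay below 0 and below the median of all genes. Vascular and cell wall genes fell in 9 of 11 cases and 1 rose, or 10 and 1 adjusted over the list alone (median −0.71, adjusted p = 0.00303). The adjusted p was 0.407 with an estimated correlation, 0.0672 with the deposited scaling and 0.0665 with median centring, and the lowest over the alternatives was 4.85e-04. The size of the median moved as well, to −1.13 with the deposited scaling, −0.47 without the first Pusa 1266 replicate, −0.35 with pseudocount 64, −0.37 with the filter at a higher percentile and −0.26 with no filter, where 20 genes were tested. The cellulose synthase genes CESA2 (−1.65), CESA6 (−1.06) and CESA8 (−0.71) and the methyltransferase gene ROMT-15 (−0.81) fell, CESA2 with Pusa 1266 signals of 17.3 and 13.3 and a value of −0.95 with pseudocount 64, and CESA4 rose by 0.47. With both other scalings all 11 lay below 0 and 10 below the median of all genes. Both marker lists moved with the 3' to 5' ratio, which for GAPDH was 19.4 in Pusa 1266 and 8.03 in Pusa Basmati 1.

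Defence genes outside the WRKY family gave short lists. Of 6 pathogenesis-related genes 2 fell and none rose, also adjusted over the list alone (median −0.41, adjusted p = 0.391). These were PBZ1, with signals of 13.4 and 8.7 in Pusa 1266 against 53.2 and 63.2, and the chitinase gene Cht6, with 0.3 and 0.4 against 17.1 and 19.6. Both peroxidase genes tested fell, also adjusted over the list alone, PRX112 at −0.48 and the other with signals of 2.3 and 0.7 against 31.7 and 18.6. The only disease resistance gene tested, Pikm2, fell with signals of 5.4 and 0.5 against 20.9 and 18.8, and its adjusted p in limma reached 0.130 without the first Pusa Basmati 1 replicate, at −0.65. Except for PRX112, these genes had Pusa 1266 signals below the added constant, so the sizes of their differences depend on it.

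**Figure D3:**
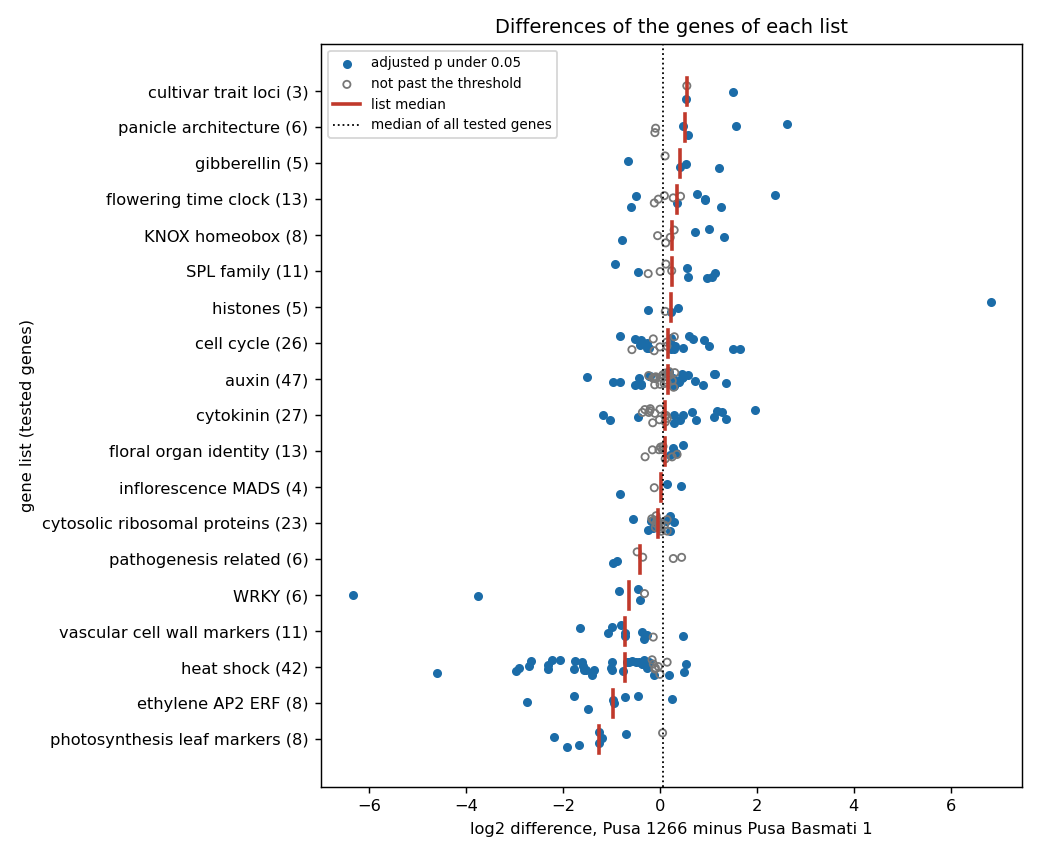
Log2 difference, Pusa 1266 minus Pusa Basmati 1 (x axis), of each tested gene of the 19 lists (y axis), filled where the adjusted p was under 0.05, with a red bar at the median of the list and a dotted line at the median of all genes. Heat shock, photosynthesis, ERF, WRKY and vascular genes lie mostly left of the line, with medians from −0.64 to −1.26.

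Along the chromosomes no clustering of the called genes was detected: 61.2% of called genes were followed by another called gene, against 61.0% by chance (9254 of 15181 genes called, 1-sided permutation p = 0.225). Without the filter on dim probe sets the share was 45.4% against 43.3% by chance (permutation p = 0.0001, the smallest 10000 reassignments can give), and without both named neighbouring copies and probe sets that match several transcripts 61.7% against 61.0% (permutation p = 0.0225). Genes at 2-fold or more, tested after the data were seen, were clustered, with 16.8% followed by another against 12.8% by chance (permutation p = 0.0001). No chromosome passed the test of its called share against the rest, and at 2-fold or more chromosome 5 had fewer such genes (odds ratio 0.74, Fisher's exact test, adjusted p = 0.0174). Chromosome 4, of prior interest because a grain number locus of Pusa 1266 had been mapped there, had 63.0% of its 1322 genes called against 60.8% elsewhere (odds ratio 1.10, Fisher's exact test, adjusted p = 0.620). RFL and RR1 lie on that chromosome. Their place relative to the mapped locus was not analysed here.

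With 2 arrays per cultivar, RNA quality, array brightness and cultivar changed together, and the design holds no array that separates them. Of 19 lists 5 passed with the preset correlation and 0 with the estimated correlation, and fry, which does not compare a list with other genes, called 18. The 0 does not show correlation between genes, because that option has few degrees of freedom with 2 arrays per cultivar. For the WRKY genes p in camera rose from 8.79e-04 to 0.0763 with it, although their estimated correlation was −0.19.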

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

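The clustering at 2-fold or more and the list medians relative to all genes were tested only after the data were seen. The calls were limited by 2 arrays per cultivar, by dim signals (55.2% to 62.5% of the probe sets of an array at 16 or less) and by the level set between arrays. Of 83 named genes 66 kept their direction and their side of the threshold with the deposited scaling, 70 with median centring, 81 with pseudocount 1, 82 with pseudocount 64, 78 with no filter and 81 with the replicate block, and so did 73 of 74 with the 75th percentile filter. All those that turned kept their sign relative to the median of all genes. The 16046 calls became 19602 with the deposited scaling, 16566 with median centring, 13320 with no filter, 11386 with the 75th percentile filter, 14705 with eBayes without trend, 16033 with its robust option, 12852 without probe sets that match several transcripts, and 16358 with the replicate block, 15812 of them shared with the fit without it. All 19 lists kept their side of the threshold with both pseudocounts, no filter, the block and a mean over all probe sets.

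With the deposited scaling 1646 probe sets were higher and 17956 lower, 619 and 7347 at 2-fold or more. With median centring these were 2906 and 13660, and 849 and 4802. A smaller constant added to the signal (pseudocount 1) gave 2793 higher and 3446 lower at 2-fold or more, and pseudocount 64 gave 786 and 1209, because the constant shrinks folds. A test against a minimum fold of 1.5 left 4239, 1881 higher and 2358 lower, a stricter hypothesis by construction.

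Reversed with the deposited scaling were SPL14 (IPA1) at −0.14, FON1 at −0.35, PHYA at −0.37, MADS50 at −0.54, MADS18 at −0.29, MADS15 at −0.35, MADS4 at −0.36, MADS2 at −0.50, MADS58 at −0.50, MADS5 at −0.54, gid1 at −0.31 and H2B.11 at −0.31. With median centring FON1 stood at −0.12, PHYA at −0.14, MADS18 at −0.057, MADS15 at −0.11, MADS4 at −0.12, MADS2 at −0.27, MADS50, called in neither fit, at −0.30, MADS58 at −0.26, MADS5 at −0.30, gid1 at −0.076 and H2B.11 at −0.077.

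The 5 lists called by camera became 0 with an estimated correlation and 18 with fry, and were 5 with each array left out. For 2 lists that camera did not call its direction turned from down to up with the other scalings, while their medians stayed below 0, at −0.48 with the deposited scaling and −0.25 with median centring for ribosomal proteins (0.13 above the median of all genes in both) and at −0.72 and −0.49 for pathogenesis-related genes (0.11 below it). The direction of the inflorescence MADS list, also not called, turned without the first Pusa Basmati 1 array, with medians of −0.034 to 0.064 as each array was left out. Among called genes 45.4% were followed by a called gene with no filter (permutation p = 0.0001) and 61.7% without named neighbouring copies and probe sets that match several transcripts (permutation p = 0.0225). At 2-fold or more the share was 16.8% (permutation p = 0.0001, the smallest 10000 reassignments can give), and also 16.8% without such copies and probe sets. Copies among genes without a name stayed in, so this does not exclude neighbouring copies as a cause. The cause was not tested.

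With 1 array left out, where the lone array is assumed to vary like the other cultivar's, the calls numbered 12908 to 14681, 6927 to 7599 higher and 5981 to 7082 lower, with 1709 to 1810 and 2327 to 2385 at 2-fold or more. No named gene turned, and at most 5 lost their call. MADS15 (0.09 to 0.20), MADS5 (0.13 to 0.29), MADS58 (0.22 to 0.46), SD1 (GA20ox2) (0.38 to 0.67) and Pikm2 (−0.94 to −0.45) each lost it with 3 of the 4 arrays left out in turn, and held it only without the first Pusa Basmati 1 array for MADS15 and MADS5, the second for MADS58, the second Pusa 1266 array for SD1 and the first for Pikm2. MADS2 lost it without the first Pusa 1266 array (0.23), and DTH8 (Ghd8) and a peroxidase gene without the first Pusa Basmati 1 array (0.65 and −0.77). MADS50 gained it without the first Pusa 1266 array (0.34) and Wx without the first Pusa Basmati 1 array (0.78).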

Other observations

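The tests of gene families and of clustering at 2-fold or more, those of the photosynthesis markers and of the longer heat shock and WRKY genes, and those of 8-fold differences by direction were chosen only after the result was seen. JAZ genes, which encode repressors of jasmonate signalling and are themselves induced by it, fell as a family in Pusa 1266. Of 11 tested JAZ genes 10 fell, 9 of them by 2-fold or more, and the median was −3.14, or −3.27 relative to the median of all genes with both other scalings. Among 146 families of genes with a shared name the JAZ family had an adjusted p of 1.96e-06 in camera, and the adjusted p was 0.899 with an estimated correlation. JAZ13 stood at −3.14 ± 0.06 (SE, n = 2 per cultivar) and JAZ6 at −3.14 ± 0.07, and JAZ6 signals were 130.9 and 140.5 against 2117 and 2351. The exception was EG2 (JAZ1), known from spikelet development, which rose by 0.62 ± 0.05 and stood at 0.09 with the deposited scaling. The jasmonate synthesis gene OG1 (OPR7) was at −0.94 ± 0.06, while the OPR family, with 3 of 5 genes lower, did not pass (adjusted p = 0.312). The same Pusa 1266 arrays had higher 3' to 5' ratios and lower photosynthesis and vascular lists (medians −1.26 and −0.71). RNA quality, tissue and cultivar cannot be told apart for the JAZ genes.

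Other named families held members that changed by more than 2-fold, but none of the families named here passed in camera. In the calmodulin-like family CML31 fell by 2.45 ± 0.06, while 10 of 22 genes fell and 2 rose (adjusted p = 0.295). NAC048 (SNAC2), a NAC factor of drought and salt tolerance, stood at −1.96 ± 0.11, with 3 of 5 NAC genes lower and 1 higher (adjusted p = 0.281). Of 10 GRF genes, which regulate leaf and organ growth, 6 rose and 1 fell (adjusted p = 0.375), with GRF12 at 1.52 ± 0.12, GRF1 at 1.48 ± 0.08 and GRF3 at −0.81 ± 0.09. GRF10 (−0.45), GRF11 (−0.29) and GRF5 (grf3, −0.59), which had risen, lay below 0 with the deposited scaling and above the median of all genes. YABBY genes rose in 4 of 5 cases (adjusted p = 0.241), with YAB6 at 1.12 ± 0.11. YAB6, YAB5 and FIL1 stood at 0.31, 0.07 and 0.05 with the deposited scaling, and FIL2 turned to −0.50, which was above the median of all genes. CML31, NAC048, GRF12, GRF1, GRF3 and YAB6 kept their sign with the deposited scaling and with median centring, and all genes named here were picked after their values were seen.

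Genes at 2-fold or more lay near one another more often than by chance. Of these genes 16.8% were followed by another, against 12.8% by chance (permutation p = 0.0001, the smallest 10000 reassignments can give), with 10.8% against 5.56% for genes higher in Pusa 1266 and 10.5% against 7.23% for genes lower. The share was 15.2% at 3 genes apart, 14.2% at 20 genes (permutation p = 0.014) and 13.1% at 50 genes (permutation p = 0.361). The densest stretch, on chromosome 10 between LOC4348016 and LOC4348063, held 12 such genes of 20, 5 higher and 7 lower (permutation p = 0.006 over 1000 reassignments). By chromosome, 14.7% of the genes of chromosome 4 were at 2-fold or more against 12.6% elsewhere (Fisher's exact test, adjusted p = 0.126), and chromosome 5 had fewer than the 13.1% elsewhere (odds ratio 0.74, adjusted p = 0.0174).

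Among control values that belong to no comparison, the poly-A spikes were lower in the second Pusa 1266 array, where dap was 106 against 756, 434 and 524 on the other arrays. The 28S ribosomal RNA signal was 11.6 and 45.1 in Pusa 1266 and 104 and 218 in Pusa Basmati 1.

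Heat shock and WRKY genes were lower in Pusa 1266, the cultivar with the higher 3' to 5' ratios. The 15 heat shock genes with a span under 1000 bases had a median 1.53 below that of the 651 tested genes of that span. All 15 fell, and the 95% interval of the difference of −1.53 was −2.27 to −0.33. Intervals here and below come from resampling genes and leave out the variation between arrays. A 3' bias shared by all genes of that span is argued against. The middle probe set of GAPDH, however, stood at −0.88 against 0.13 at its 3' end, and that of cyclophilin at −0.10 against 0.04. Probe position within a short gene could therefore account for part of the difference, and 3' bias is not excluded. With median centring the 48 members lay at −0.76 (−1.48 to −0.49) relative to all genes, and the deposited scaling gives the same value by construction. A constant shift between arrays cancels in this difference, so such a shift cannot account for it. For the WRKY genes and the longer heat shock genes the difference was −0.58 (−1.07 to −0.40, 33 genes). The widest gap between the ends of a control transcript, that of the second actin design, was −1.31, and the other controls had smaller gaps. As −0.58 was smaller than that widest gap, 3' bias and cultivar cannot be told apart for these 33. A cultivar difference, or a difference in stress or handling at collection, may underlie the set as a hypothesis, and neither was tested. The photosynthesis and vascular lists fell on the same arrays (medians −1.26 and −0.71), and tissue make-up was not tested for this set either.

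Genes at 8-fold or more could reflect probes that match only the sequence of 1 cultivar. In 24 of the 168 genes another probe set with another consensus sequence was tested. Its median difference in the direction of the first was 1.63 (95% interval over genes 0.88 to 2.80), which argues against probe sequence as the only cause for the set. The 8-fold probe sets of these 24 genes had a median of 3.91, so the difference was smaller in the other probe sets. Probe sequence may therefore account for part of the size. Of the 24 genes 15 stood at 1 or more and 4 under 0.3, so single genes may differ. Another probe set of LOC4333210 was called in the opposite direction. By direction the median was 2.78 (1.06 to 3.603) in 16 of the 101 lower genes, against 4.13 for their 8-fold probe sets. In 8 of the 67 higher genes the median was 0.83 (0.08 to 1.89), against 3.41 for their 8-fold probe sets, so probe sequence stays open for those. H2B.10, KIN14R, PMEI28 and SPO11-4 had no other tested probe set. A difference between the cultivars in expression or in gene content remains open and untested.

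Photosynthesis genes may be lower because there was less green tissue in the dissected primordia of Pusa 1266. All 3 markers with a mean log2 signal over 8, CAB2R, LHCP and OEE3, were lower by more than 2 SE, but PSAG at 0.05 ± 0.09 did not pass at a signal just below that level, and cultivar and RNA quality change together for all of them. Dissection, stage and cultivar therefore cannot be told apart for these genes.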
